A study of Mus musculus with 4 samples.

How the data were processed

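Nuclei of whole mouse hearts at E15.5 were captured and barcoded on the 10x Genomics platform and sequenced as 5′ gene expression libraries, per the labels' protocols. Groups came from the labels: 2 control libraries and 2 knockout libraries, 1 male and 1 female in each group. How many hearts entered a library was not given in the sources used here. The authors deposited, for each library, a matrix of raw UMI counts per gene and barcode with its gene and barcode lists. A UMI count is the number of distinct captured molecules, without normalization. The reads were counted with Cell Ranger, given as version 7.1.0 per the file headers and as version 3.1.0 per the submitters' processing notes, on mm10 per the same notes. Deposited barcodes started at 500 UMIs, so near-empty droplets could not be used to measure free RNA. The gene lists held 32287 features, of which 32158 were found by identifier in GENCODE vM21. Coordinates are from that annotation of mm10, and they include Cre and GFP as added features without coordinates.

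Barcodes were kept with at least 500 UMIs, at least 300 detected genes and at most 5% of UMIs from mitochondrial genes, which left 16639, 19160, 14117 and 15971 barcodes in the library labelled male control and in the male knockout, female control and female knockout libraries. Doublets were marked per library with Scrublet through scanpy 1.11.5, with an expected share of 10% and the score limit that Scrublet set for each library. It marked 15.5%, 18.7%, 7.3% and 14.1% of these barcodes in the same order, and they were removed. A total of 56449 nuclei was analysed, 14059, 15579, 13090 and 13721 per library, with median UMI counts of 4051, 3892, 4841.5 and 3639.

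Counts were scaled to 10000 per nucleus and log-transformed, and 3000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, resolution 1.5, seed 0) gave 36 clusters. Xist, Y-linked, mitochondrial and globin genes, Numb, Numbl and Tbx18 were kept out of the clustering. Clusters were named "X-like" from marker lists fixed beforehand. A marker counted when its level was at least 2 times that of the other nuclei and it was detected in at least 10% of the cluster, and at least 3 such markers were required. The top 10 genes of each cluster were ranked by fold with a pseudocount of 50 CPM among genes detected in at least 25% of its nuclei, and had to hold no more markers of another class than of the cluster's own. Shares of 0.25 of the cardiomyocyte markers and 0.5 of the endothelial markers were asked for before a subtype was named. Clusters whose median UMI count lay under 0.333 of that of their libraries stayed unnamed, clusters with over 45% marked doublets were left out, and a ventricular cluster with a median mitochondrial share over 2.5% was kept as a class of its own.

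These naming limits were chosen after the clusters had been seen, while the markers were not. The pseudocount of 50 replaced 1 because with 1 the top 10 genes of cluster 6, the fibroblast-like class, held 1 mural marker (Ebf2) and no fibroblast marker. With 50 they hold 1 of each, and 16 of its 20 fibroblast markers passed. The values of that class are those of cluster 6 under any name. Low-UMI clusters were left unnamed even where their own markers led them, and naming them is an alternative added after seeing the data. The added alternatives also comprise 1 doublet score limit of 0.2 for all libraries, the mitochondria-rich cluster joined to the ventricular class, each mural cluster alone, clusters made without the changed genes, and the nuclei of named classes as library size. Leading genes of a cluster are not reported as changes within its class.

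For each class with at least 20 nuclei in every library, raw counts were summed per library, and the sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalization, filterByExpr, R 4.3.3), knockout against control without covariates. Nuclei were not treated as replicates. P-values were adjusted by the Benjamini-Hochberg method over the genes of a class, at a threshold of 0.05. Fold changes are log2 of knockout over control with standard errors (SE) from the fit, levels are CPM, counts scaled to the same library total, as mean ± SD of 2 libraries, and all tests were two-sided. Shares of nuclei were tested with the same edgeR test on nuclei per class and by exact permutation, whose smallest p is 0.333 with 2 libraries against 2. A set of 32 gene lists was tested with camera (limma 3.58.1, preset correlation 0.01), and each call was repeated with the correlation estimated from the data and with fry. With groups of 2 libraries, other splits of the samples and single stray libraries could not be tested. Intervals of the Cre and GFP counts are exact 95% Poisson intervals, a count of 0 is given with the level that 3 UMIs would have, and both cover counting error only.

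The marker lists, the gene lists, the tests, the other settings and the rule for named genes were fixed before the data were examined. That rule names Numb, Numbl and Tbx18 in every class, and the 10 genes with the smallest adjusted p in each direction among those past the threshold that moved the same way in the male and the female pair. Where fewer than 5 pass in both directions together, it names the 5 with the smallest p in each direction, said not to pass. Not every gene that the rule names is printed below. From each gene list that was called it takes up to 4 members with the smallest p, and genes without a symbol, Xist and Y-linked genes are skipped. Other genes are said to have been chosen after their values were seen. Other settings fixed beforehand were DESeq2 1.42.0 as a test and as a scaling, no filter on low counts, the replicate number as a block, leaving out each library, keeping doublets, a stricter filter of 1000 UMIs, 600 genes and 1% mitochondrial UMIs, and only nuclei with at least 80% of their neighbours in the same class.

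The test was run on simulated counts drawn from the real means and library sizes with known fold changes of 1.5, 2 and 4. Of the genes simulated at these folds it recovered 40.9%, 81.8% and 98.5% in epicardial-like sums (14015 genes), 33.3%, 74.2% and 96.9% in fibroblast-like sums (12953 genes), 54.5%, 86.6% and 98.5% in ventricular sums (15261 genes), and 13.8%, 53.8% and 89.1% in mural-like sums (12672 genes). The corresponding shares were 28.8%, 69.7% and 96.8% for atrial sums (11071 genes), 54.5%, 76.2% and 95.4% for endocardial-like sums (14436 genes), 32.8%, 70.8% and 98.4% for coronary sums (11704 genes), and 49.2%, 87.3% and 96.9% for all nuclei (19521 genes). Genes simulated without a change were called too: 12 in epicardial-like, 15 in fibroblast-like, 17 in ventricular, 16 in mural-like, 6 in atrial, 7 in endocardial-like and 17 in coronary sums and 21 in all nuclei. As a share of all calls this is above the threshold of 0.05 everywhere except in atrial and endocardial-like sums. Other software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.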

Results

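Single nuclei were profiled from whole mouse hearts at E15.5, while the ventricular wall is compacting. Knockout embryos carried Cre recombinase at Tbx18, which encodes a T-box transcription factor of the epicardium, the mesothelial sheet that covers the heart. They were also homozygous for floxed alleles of Numb and Numbl (Numblike), which encode endocytic adaptor proteins known as regulators of Notch signalling. Control embryos are described as lacking Cre. The comparison of 2 control with 2 knockout libraries, each group with 1 male and 1 female library, asks how loss of these proteins from the epicardium affects compaction and the other cell types of the heart. As described, the knockouts also differ from the controls in the Tbx18 allele with Cre. Effects of that allele and of the loss of Numb and Numbl cannot be told apart here. The deposited matrices held 100.6 M UMIs in the library labelled male control, 121.5 M in the male knockout, 97.5 M in the female control and 101.5 M in the female knockout library, over 26129, 27708, 21235 and 25170 barcodes.

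Cre transcripts were present in both knockout libraries and in the library labelled male control, and none was found in the female control library. The nuclei analysed held 1087 Cre UMIs in the male knockout, 931 in the female knockout and 531 in the library labelled male control. The female control library held 0, which allows a level of up to 0.0416 CPM. In epicardial-like nuclei Cre stood at 26.2 and 22.4 CPM in the male and female knockouts and at 6.24 (95% Poisson interval 4.00 to 9.28) in the library labelled male control. Cre was not limited to that class. Endocardial-like nuclei held 16.6 and 16.3 CPM in the male and female knockouts and 10.6 in the library labelled male control. In the same order, the values were 16.6, 15.3 and 10.7 in coronary endothelial-like nuclei. They were 19.5, 18.8 and 13.8 in mitochondria-rich ventricular nuclei, and lower in ventricular cardiomyocyte-like nuclei (9.59, 8.18 and 5.7). GFP, a fluorescent reporter transcript whose construct is not given in the sources used here, reached 68.6 (62.5 to 75.2) and 76.6 (69.6 to 84.1) CPM in epicardial-like nuclei of the male and female knockouts, against 2.86 in the library labelled male control and 3.08 in the female control. In fibroblast-like nuclei GFP stood at 21.2 and 19.2 CPM in the knockouts and at 2.42 and 4.39 in the controls. It was higher than that in mitochondria-rich ventricular nuclei of the knockouts (27.02 and 35.8, controls 0 and 1.78) and close to it in valve mesenchyme-like nuclei (17.96 and 21.5, controls 2.35 and 3.28). The Cre count goes against the label of 1 of the 2 control libraries, and every control mean includes that library. Counts of called genes without it are therefore given beside each comparison of expression, but not beside the list and share tests.

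**Figure D1:**
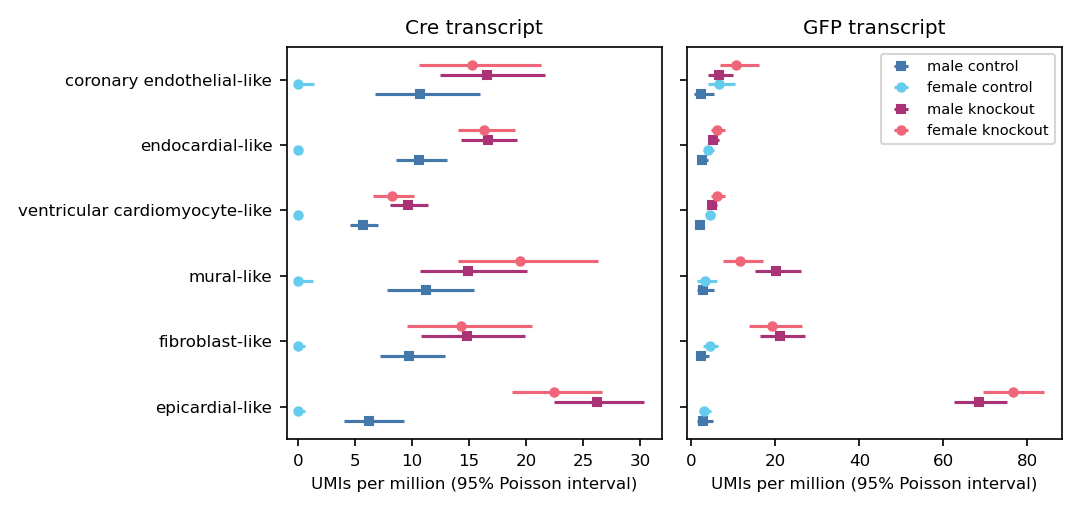
Cre (left) and GFP (right) levels in CPM (x axes) in 6 classes of nuclei, with 1 point per library and exact 95% Poisson intervals. GFP in epicardial-like nuclei is 68.6 and 76.6 in the knockouts and 2.86 and 3.08 in the controls, while Cre in the library labelled male control lies above 0 in these classes.

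Neither targeted gene passed the test in any class. In epicardial-like nuclei Numb (chromosome 12, 83794034 to 83921934) had a log2 fold change of 0.13 (SE 0.13, adjusted p = 0.702) and Numbl (chromosome 7, 27258433 to 27282144) one of -0.15 (SE 0.14, adjusted p = 0.663). A 5′ library need not read the floxed exons, so these levels check neither the deletion nor the labels. Tbx18 (chromosome 9, 87702800 to 87731260), of which the knockouts have 1 allele with Cre, fell in epicardial-like nuclei by 0.78 on the log2 scale (SE 0.14, adjusted p = 0.00762), from 457.4 ± 8.2 to 266.8 ± 38.6 CPM, and in atrial cardiomyocyte-like nuclei by 1.38 (SE 0.26, adjusted p = 0.0469). Tbx18 CPM in epicardial-like nuclei was 463.2 in the library labelled male control and 451.6 in the female control, against 294.1 and 239.5 in the male and female knockouts. Without the female knockout library the epicardial call was lost (-0.64, adjusted p = 0.209). The atrial call of Tbx18 was lost without the same library (adjusted p = 0.34), with DESeq2 size factors (0.0518), with DESeq2 (0.994), with doublets kept (0.254), under the stricter nuclei filter (0.22), with pure neighbours (0.0849) and with 1 doublet limit (0.103).

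Epicardial-like nuclei had more called genes than any other class: 532 genes rose and 465 fell among 14211 tested, all in the same direction in the male and the female pair. Called genes of every class did so, since a call with so few libraries nearly requires it. The agreement of the pairs is therefore no separate replication. Pdgfra, the alpha receptor for platelet-derived growth factor (chromosome 5, 75152292 to 75198215), rose by a log2 fold change of 1.92 (SE 0.13, adjusted p = 3.97e-05), from 34.9 ± 3.45 to 132.9 ± 8.23 CPM, and its ligand Pdgfc rose by 1.93 (SE 0.13). Fgfr1, a fibroblast growth factor receptor (chromosome 8, 25513654 to 25575718), rose by 1.99 (SE 0.13), from 30.9 ± 2.24 to 123.4 ± 12.3 CPM. Shc3, an adaptor of receptor tyrosine kinases, rose by 2.69 (SE 0.15).

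The other genes with the smallest p among those that rose were Tmem132d, a transmembrane protein gene on chromosome 5 (127781630 to 128433077), at 4.17 (SE 0.21, adjusted p = 1.94e-05, from 9.87 ± 3.79 to 170.3 ± 22.3 CPM), and Car4, a membrane carbonic anhydrase, at 3.37 (SE 0.18). Ano3, of the anoctamin membrane proteins, rose by 4.92 (SE 0.31), the zinc-finger gene Zfp536 by 2.83 (SE 0.19), Fli1, an ETS factor known from endothelial and blood cells, by 2.45 (SE 0.14), and the metalloprotease gene Adam19 by 1.83 (SE 0.12). Among those that fell were Asic2, a proton-gated ion channel (-2.89, SE 0.20), Chrdl1, a secreted antagonist of BMP (-2.69, SE 0.18), Ptger3, a prostaglandin E receptor (-2.09, SE 0.14), and Tll1, a protease that cleaves chordin (-1.96, SE 0.14). Mctp1 (-2.07, SE 0.16), the thyroid hormone receptor gene Thrb (-1.81, SE 0.14), Cybrd1, a ferric reductase (-1.77, SE 0.14), Ccdc85a (-1.66, SE 0.12) and the potassium channel gene Kcnd2 (-1.63, SE 0.12) fell too.

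**Figure D2:**
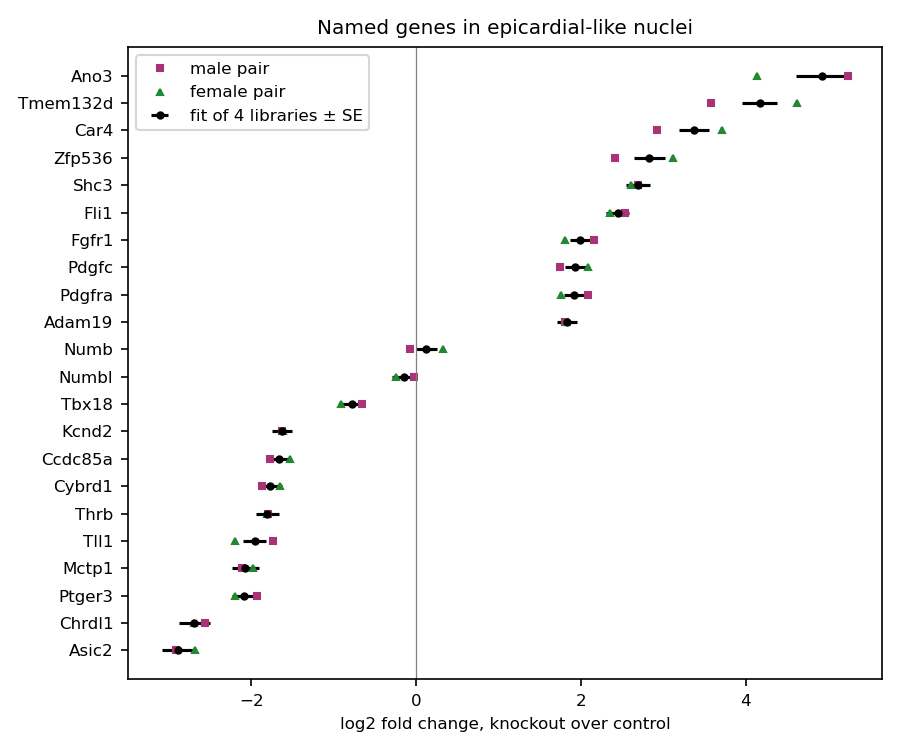
Log2 fold change of knockout over control (x axis) for the named genes in epicardial-like nuclei (y axis), with the estimate from 4 libraries ± SE and the male and female pairs as separate points. Ano3 (4.92) and Asic2 (-2.89) mark the ends of the range, and both pairs lie on the same side of 0 for each gene shown except Numb.

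Of 32 gene lists, 3 were called in epicardial-like nuclei. Feedback genes of receptor tyrosine kinase signalling rose together (median log2 fold change 1.00, adjusted p = 1.38e-06, and adjusted p = 0.915 with an estimated correlation): 5 of 11 measured members rose and none fell, 8 when adjusted over the list alone. Dusp4, a MAP kinase phosphatase, rose by 2.48 (SE 0.30), the signalling inhibitors Spry4 and Spry1 by 1.95 (SE 0.25) and 1.23 (SE 0.18), and Etv5, an ETS factor downstream of FGF, by 1.53 (SE 0.17). Genes of epithelial-mesenchymal transition were higher as a list (median 0.28, adjusted p = 0.00151, and adjusted p = 0.837 with an estimated correlation). Of its 23 members 6 rose and 1 fell, 11 and 1 when adjusted over the list alone, among them Pdgfra, the matrix protease gene Mmp2 (1.40, SE 0.11), Tagln, an actin-binding protein of smooth muscle (1.51, SE 0.31), and Zeb2, a repressor of epithelial genes (0.55, SE 0.12). The epicardial identity list was lower (median -0.40, adjusted p = 0.00134, and adjusted p = 0.837 with an estimated correlation), with 4 of 15 members lower and 1 higher, 9 and 1 when adjusted over the list alone. Aldh1a2, which makes retinoic acid, fell by 0.85 (SE 0.13, from 662.1 ± 6.74 to 367.8 ± 0.34 CPM), and Tcf21, a transcription factor of epicardium and its fibroblast lineage, rose by 0.90 (SE 0.16). Tbx18, of which the knockouts have 1 allele with Cre, is 1 of the 4 lower members. Its fall is therefore no separate evidence of a change in identity, and the list was not tested without it. Several members of the epicardial identity list, such as Upk3b and Wt1, also lead the cluster and are counted in the list without being reported singly.

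**Figure D3:**
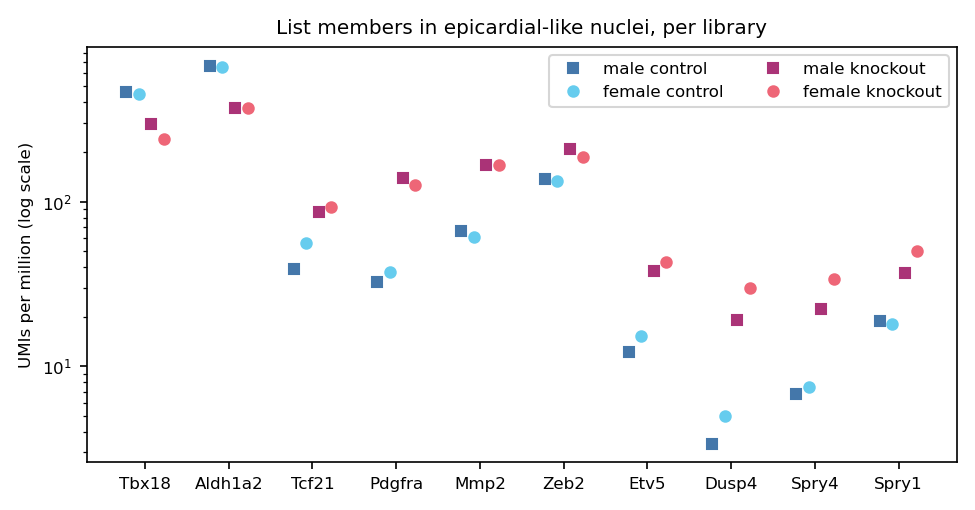
CPM (y axis, log scale) of 10 list members in epicardial-like nuclei, 1 point per library. Aldh1a2 lies at 662.1 ± 6.74 in the controls and 367.8 ± 0.34 in the knockouts, and Pdgfra at 34.9 ± 3.45 and 132.9 ± 8.23.

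Abundant cardiomyocyte RNA (median 0.12, adjusted p = 0.435) and mitochondrially encoded RNA (median -0.21, adjusted p = 0.0654) were not called in this class. DESeq2 called 711 genes. The count was 1573 without the library labelled male control, 596 without the male knockout and 569 without the female knockout library.

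Fibroblast-like nuclei, the mesenchyme that in the heart derives largely from the epicardium, had 159 genes higher and 160 lower among 13146 tested. Kif26b, a kinesin family gene (chromosome 1, 178529125 to 178939200), rose by a log2 fold change of 1.99 (SE 0.14, adjusted p = 3.73e-05), from 29.7 ± 3.61 to 119.7 ± 21.5 CPM. Also higher were Unc13c, a vesicle priming gene (1.53, SE 0.19), Ano3 (1.46, SE 0.15), Etl4 (1.32, SE 0.13), the adenylyl cyclase gene Adcy2 (1.26, SE 0.16), Pawr, known in apoptosis (1.13, SE 0.14), the myosin gene Myo1d (1.09, SE 0.14), the kinase gene Dclk1 (1.03, SE 0.09), Frmd4b (0.96, SE 0.10) and Sfrp2, a secreted Wnt modulator (0.79, SE 0.08). Genes that fell included Tmtc1 (-1.44, SE 0.14), the talin gene Tln2 (-1.17, SE 0.11), Slc24a2, a cation exchanger (-1.15, SE 0.09), Nav3 (-1.05, SE 0.09), the kainate receptor gene Grik2 (-0.92, SE 0.08) and the cell adhesion gene Ntm (-0.86, SE 0.09). Hpse2, Prlr and Cdh10 met the same rule but lead the cluster and are not reported as changes within it.

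In fibroblast-like nuclei 15 lists were called, and none of these calls held with an estimated correlation. Mitosis genes were higher (median 0.40, adjusted p = 2.52e-11, and adjusted p = 0.502 with an estimated correlation), with 4 of 22 members past the test and 18 when adjusted over the list alone. Among them were Mki67, a proliferation marker (0.46, SE 0.08), Top2a (0.37, SE 0.08) and Tpx2, a spindle factor (0.44, SE 0.10). Clusters made without the changed genes split this class into a cluster 10 and a cluster 21, the latter with the proliferation marker Diaph3 among its leading genes. With marked doublets included, cluster 21 held 230 and 206 nuclei in the male control and knockout and 238 and 161 in the female ones. Cluster 10 held 755, 418, 800 and 285 in the same order, a difference in mix that was not tested. Glycolysis genes were higher (median 0.33, adjusted p = 0.000129, and adjusted p = 0.592 with an estimated correlation): 4 of 15 rose and none fell, 9 when adjusted over the list alone, including Eno1 (0.63, SE 0.11), Pgk1 (0.57, SE 0.11), Ldha (0.46, SE 0.10) and Tpi1 (0.39, SE 0.09). Of 11 smooth muscle contractile genes 3 rose, 5 when adjusted over the list alone (median 0.60, adjusted p = 0.000112, and adjusted p = 0.555 with an estimated correlation), namely Mylk (0.93, SE 0.14), Acta2 (0.64, SE 0.11) and Synpo2 (0.60, SE 0.13). Wnt genes (median 0.22, adjusted p = 0.00895, and adjusted p = 0.555 with an estimated correlation) included Sfrp2, Sfrp1 (0.50, SE 0.10) and Wnt11 (1.19, SE 0.23) as the 3 of 17 that rose, 4 when adjusted over the list alone. In the BMP and TGF-beta list (adjusted p = 0.00537, and adjusted p = 0.655 with an estimated correlation) 2 of 19 rose in either count, among them Id3 (0.44, SE 0.08). Among further members of called lists, the vascular growth factor gene Vegfc (0.61, SE 0.08), its receptor family gene Flt1 (1.26, SE 0.16) and Nppa, which encodes atrial natriuretic peptide (0.63, SE 0.11), rose. In the same nuclei abundant cardiomyocyte RNA was higher (median 0.24, adjusted p = 0.0401, and adjusted p = 0.754 with an estimated correlation), as was the sarcomere list (adjusted p = 0.00046, and adjusted p = 0.655 with an estimated correlation), and mitochondrially encoded RNA was lower (median -0.20, adjusted p = 0.0129, and adjusted p = 0.811 with an estimated correlation). DESeq2 called 154 genes. Without the male knockout library the count was 489, and without the library labelled male control it was 390.

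**Figure D4:**
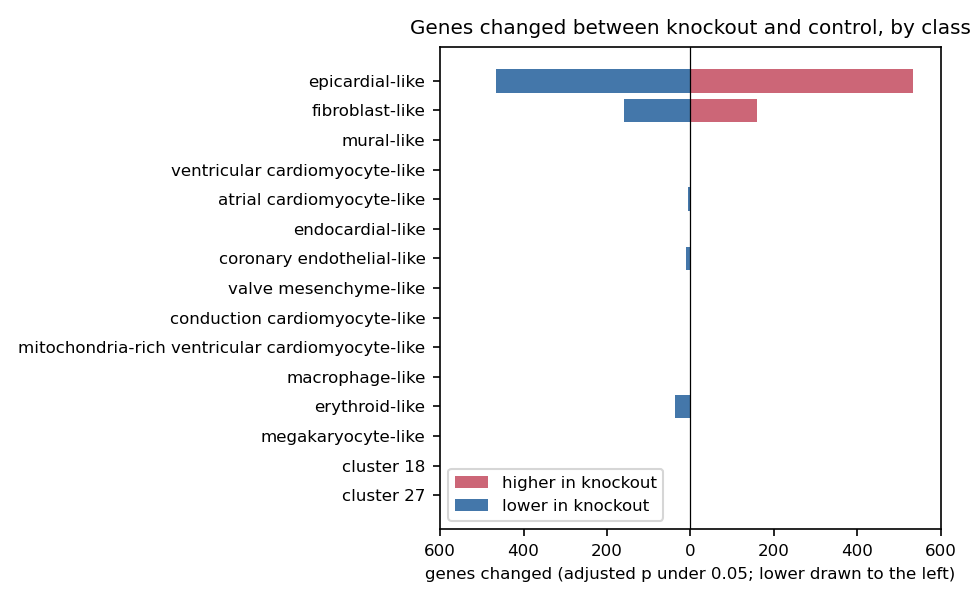
Number of genes changed between knockout and control (x axis, adjusted p under 0.05, lower drawn to the left) in each class of nuclei (y axis). Epicardial-like nuclei have 532 higher and 465 lower, fibroblast-like nuclei 159 and 160, and ventricular cardiomyocyte-like nuclei 1 and 1.

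The share of fibroblast-like nuclei was lower in both knockout libraries. With clusters made without the changed genes, it was 7.03% ± 0.975 of nuclei in the controls and 3.27% ± 0.426 in the knockouts (SD of 2 libraries), a log2 fold change of -1.11 (SE 0.24) with an edgeR adjusted p = 0.0308. The exact two-sided permutation p = 0.333 is the smallest that this design can give. The call rests on leaving low-UMI clusters unnamed: with these named, the log2 fold change was -0.70 and adjusted p = 0.254. With the clusters made with all variable genes the log2 fold change was -1.24 (edgeR adjusted p = 0.00771). That call was lost without the female control and without the female knockout library. No other class passed with clusters made without the changed genes. Ventricular cardiomyocyte-like nuclei were 20.7% ± 1.8 in the controls and 14.6% ± 1.78 in the knockouts (adjusted p = 0.392), and epicardial-like nuclei 4.47% ± 0.622 and 5.51% ± 0.0553 (adjusted p = 0.481). Under the stricter nuclei filter, applied to the clusters made with all variable genes, the epicardial-like share was higher in the knockouts (log2 fold change 1.02, adjusted p = 0.000182). Without that filter the same clusters gave 0.29 (adjusted p = 0.862). The filter allows 1% mitochondrial UMIs, and the epicardial-like cluster had a median of 1.29%. It kept 209 of 562 nuclei in the male control and 355 of 858 in the male knockout. In the female control it kept 135 of 660 and in the female knockout 329 of 761. The difference may therefore follow the filter.

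Unnamed low-UMI clusters held 27.3% ± 7.33 of control and 35.95% ± 0.08 of knockout nuclei, doublet-rich clusters 3.76% ± 1.8 and 3.11% ± 1.24, and the mitochondria-rich ventricular cluster 3.69% ± 1.38 and 5.38% ± 1.7. The low-UMI cluster led by fibroblast markers held 2.96% ± 0.27 and 2.53% ± 0.66. The shares in this paragraph come from the clusters made with all variable genes, unlike the shares given above as mean ± SD. A difference in these parts can shift every other share.

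**Figure D5:**
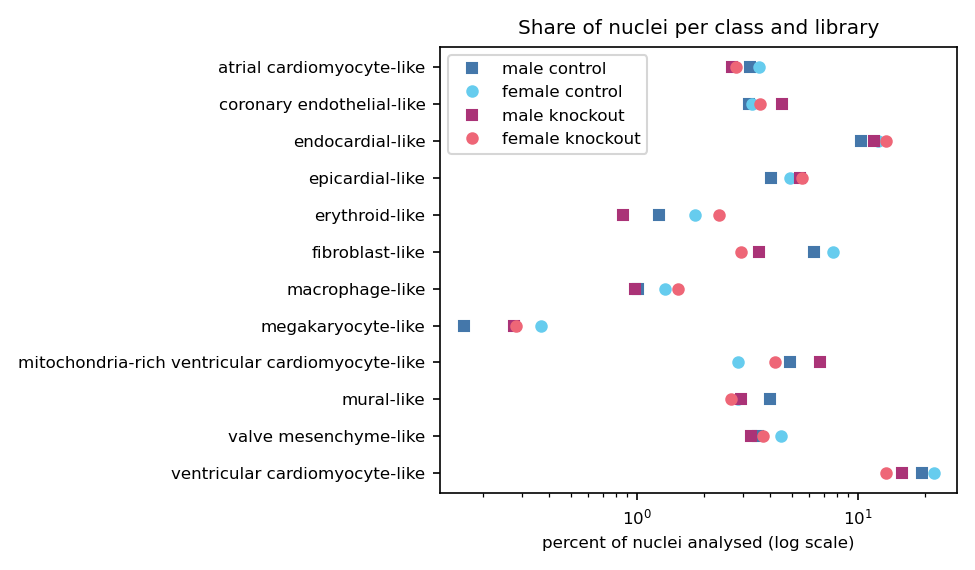
Percent of nuclei analysed (x axis, log scale) in each named class (y axis), 1 point per library, from clusters made without the changed genes and without drawing the low-UMI, doublet-rich and unnamed clusters. Fibroblast-like nuclei are 7.03% ± 0.975 in the controls and 3.27% ± 0.426 in the knockouts.

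Ventricular cardiomyocyte-like nuclei, the muscle of the compacting wall, had 1 gene higher and 1 lower among 15485 tested. Nmnat3, which encodes a mitochondrial enzyme of NAD synthesis (chromosome 9, 98287435 to 98420438), fell by 1.28 on the log2 scale (SE 0.09, adjusted p = 0.000176), from 81.0 ± 0.669 to 33.3 ± 3.97 CPM. Sntg2, a syntrophin gene (chromosome 12, 30174482 to 30373375), rose by 1.29 (SE 0.13, adjusted p = 0.00807), from 16.4 ± 2.6 to 40.1 ± 6.31 CPM. The next by p did not pass: Ppp1r10 at 0.51, Kctd16 at 0.41, Anln at 0.38 and Adgrb3 at 2.24, and in the other direction Tbx18 at -0.94 (adjusted p = 0.0754), Hmgn3 at -0.53, Ust at -0.51 and Col6a1 at -0.66. Tbx18 in these nuclei passed without the filter on low counts (adjusted p = 1.16e-21) and with any 1 library left out (adjusted p = 3.33e-05 to 0.0369).

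In these nuclei none of 12 compact myocardium genes passed (median -0.02, adjusted p = 0.852) and none of 15 trabecular myocardium genes did (median 0.14, adjusted p = 0.11), with 0 and 1 when adjusted over the list alone. Mitosis genes were higher as a list (median 0.22, adjusted p = 6.47e-09, and adjusted p = 0.799 with an estimated correlation). None of its 22 members passed, 13 did when adjusted over the list alone, and Hmmr, Ube2c and Ccna2 stood at 0.34, 0.30 and 0.32. Cluster 8, led by cell cycle genes, was 23.4% of this class in the male control, 26.6% in the male knockout, 27.5% in the female control and 29.9% in the female knockout library. Glycolysis genes were higher (adjusted p = 0.0184) and pericyte genes lower (adjusted p = 0.00301), each with adjusted p = 0.799 with an estimated correlation, no member past the test and 2 higher and 1 lower when adjusted over the list alone. Mitochondrially encoded RNA was lower (median -0.19, adjusted p = 0.000197, and adjusted p = 0.799 with an estimated correlation). This depends on leaving out the mitochondria-rich cluster: with it included, mt-Atp8 in ventricular cardiomyocyte-like nuclei stood at 0.06, mt-Cytb in ventricular cardiomyocyte-like nuclei at 0.12, mt-Co3 in ventricular cardiomyocyte-like nuclei at 0.14 and mt-Nd4 in ventricular cardiomyocyte-like nuclei at 0.25. The count of changed genes was 15 with DESeq2, and 1259 had an unadjusted p under 0.05. It was 205 without the library labelled male control, 65 without the male knockout, 68 without the female control and 6 without the female knockout library.

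Atrial cardiomyocyte-like nuclei had 2 genes higher and 6 lower among 11274. Nppa, atrial natriuretic peptide, rose by 0.62 (SE 0.10, adjusted p = 0.0219) and Dcc, a netrin receptor, by 0.98 (SE 0.19, adjusted p = 0.049). The rise of Nppa was not particular to this class. It was called in epicardial-like (0.55) and fibroblast-like nuclei (0.63) too, and it is a leading gene of unnamed low-UMI clusters. Whether free RNA accounts for the rise was not tested. Besides Tbx18, the genes that fell were Ccn1, a secreted matricellular protein (-1.12, SE 0.18), the teneurin gene Tenm3 (-1.12, SE 0.19), the ephrin gene Efna5 (-0.61, SE 0.11), the transcription factor gene Ebf1 (-1.04, SE 0.18) and the protocadherin gene Pcdh9 (-0.79, SE 0.15). Mitosis genes were higher as a list (median 0.34, adjusted p = 2e-04), extracellular matrix genes (median -0.16, adjusted p = 0.0025) and pericyte genes (median -0.77, adjusted p = 0.000209) lower, each with adjusted p = 0.918 with an estimated correlation. No member of these lists passed, and adjusted over the list alone 7 mitosis genes were higher, 4 matrix genes lower and 1 higher, and 3 pericyte genes lower. The fibroblast markers were lower beside them (median -0.37, 15 of 17 lower). DESeq2 called 2 genes, and no gene passed with doublets kept or under the stricter nuclei filter. The count was 85 without the library labelled male control, 36 without the male knockout, 57 without the female control and 3 without the female knockout library.

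Endocardial-like nuclei, the inner lining of the heart, had 2 genes past the test among 14646. Hist1h1b, a linker histone made in S phase, rose by 0.66 (SE 0.08, adjusted p = 0.0358). The other, Nav3, leads a cluster of this class and is not reported as a change. Values below the test were 0.69 for Hist1h2bn, 0.50 for Hist1h1d, -0.38 for Bckdhb and -0.34 for Lrrc1. Mitosis genes were higher as a list (median 0.33, adjusted p = 4.57e-12), as were oxidative phosphorylation (median 0.21, adjusted p = 0.000137) and glycolysis genes (median 0.26, adjusted p = 0.00289), each with adjusted p = 0.741 with an estimated correlation. No member passed, and 14, 10 and 6 were higher when adjusted over the list alone, with Top2a at 0.44, Ccna2 at 0.54, Atp5o at 0.32 and Ldha at 0.37. Cluster 29, led by cell cycle genes, was 4.7% of this class in the male control and 6.5% in the male knockout, and 5.2% in the female control and 6.6% in the female knockout, a difference that was not tested. Mitochondrially encoded RNA was lower beside them (median -0.17, adjusted p = 0.0269, and adjusted p = 0.741 with an estimated correlation). DESeq2 called 13 genes, and no gene passed in edgeR with doublets kept or under the stricter nuclei filter. The count was 87 without the library labelled male control, 58 without the male knockout, 9 without the female control and 22 without the female knockout library.

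Coronary endothelial-like nuclei had 1 gene higher and 11 lower among 11912. Nostrin, which regulates traffic of the endothelial nitric oxide synthase, rose by 0.99 (SE 0.11, adjusted p = 0.0295). Fallen genes were Kirrel3 (-2.75, SE 0.23), Adamts18 (-2.70, SE 0.32), the netrin receptor gene Unc5c (-2.40, SE 0.23), the homeobox gene Lhx6 (-1.64, SE 0.19), Negr1 (-1.47, SE 0.18), the ephrin receptor gene Epha4 (-1.34, SE 0.15), Samd5 (-1.01, SE 0.13), Tox (-0.77, SE 0.09), and the collagen genes Col3a1 (-0.99, SE 0.13) and Col5a1 (-0.94, SE 0.13), besides Egfem1. Kirrel3 and Unc5c also lead the valve mesenchyme-like cluster, and the fibroblast markers had a median of -0.72 in these nuclei.

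Extracellular matrix genes were lower as a list in coronary endothelial-like nuclei (median -0.65, adjusted p = 1.36e-08, and adjusted p = 0.509 with an estimated correlation), with 2 of 30 members past the test and 15 lower and 1 higher when adjusted over the list alone. Sarcomere genes were lower too (median -0.65, adjusted p = 9.74e-09, and adjusted p = 0.515 with an estimated correlation; none of 24 past the test, 17 when adjusted over the list alone). Abundant cardiomyocyte RNA (median -0.60, adjusted p = 8.28e-06, and adjusted p = 0.509 with an estimated correlation) and mitochondrially encoded RNA (median -0.37, adjusted p = 7.53e-05, and adjusted p = 0.531 with an estimated correlation) were lower beside these groups. The count of changed genes was 51 with DESeq2, 49 with doublets kept and 52 with 1 doublet limit. It was 183 without the library labelled male control, 30 without the male knockout, 41 without the female control and 63 without the female knockout library.

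Mural-like nuclei, the pericytes and smooth muscle of vessel walls, had no gene past the edgeR test among 12888, while 540 had an unadjusted p under 0.05 and DESeq2 called 2. The lowest p-values belonged to the muscarinic receptor gene Chrm3 (-1.57, adjusted p = 0.144), the collagen gene Col23a1 (-1.81, adjusted p = 0.182) and the kainate receptor gene Grik3 (0.88, adjusted p = 0.506). Pericyte genes were lower as a list (median -0.26, adjusted p = 0.0336) and glycolysis genes higher (median 0.14, adjusted p = 0.0231), each with adjusted p = 0.859 with an estimated correlation and no member past the test in either count. The pericyte member Ebf2 stood at -0.51, and members that lead cluster 25 are not given singly. This class joins cluster 17, led by smooth muscle genes, and cluster 25, led by pericyte genes, and cluster 25 made up 32.4% and 37.2% of it in the male control and knockout but 53.7% and 26.8% in the female control and knockout. Mitochondrially encoded RNA was lower beside them (adjusted p = 0.0476, and adjusted p = 0.859 with an estimated correlation). The count was 167 without the library labelled male control and 4 without the female control library.

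In the other classes 42 genes passed in all. Erythroid-like nuclei had 37 genes lower and none higher among 6449, led by Glis3 (-3.69, SE 0.49), Nrxn3 (-2.16, SE 0.30) and Col23a1 (-2.36, SE 0.39), names chosen after their values were seen. DESeq2 called 6 of its genes lower, and edgeR called 0 with doublets kept and 3 lower without the male knockout library. It called 6 higher and 47 lower without the library labelled male control, 21 and 49 without the female control and 17 and 68 without the female knockout library. Nrxn3 and Col23a1 are also leading genes of endocardial-like clusters. Erythroid-like nuclei join clusters 23 and 33, whose mix differed between groups. Cluster 33 was 12.6% of the class in the male control and 7.3% in the male knockout, and 13.9% and 5.9% in the female control and knockout. Its median was 6192.5 UMIs against 2005 in cluster 23, and 21.4% against 0.2% of its barcodes had been marked as doublets. How far this mix accounts for the lower genes was not tested. Nt5e, an enzyme that makes adenosine, rose in valve mesenchyme-like nuclei (1.68, SE 0.21, adjusted p = 0.0106) and in cluster 27 (2.46, SE 0.37, adjusted p = 0.0447). It fell in epicardial-like (-1.44, SE 0.33, adjusted p = 0.0244) and fibroblast-like nuclei (-0.96, SE 0.18, adjusted p = 0.0144). No gene was called in cluster 27 with DESeq2, and none in cluster 27, cluster 18 or valve mesenchyme-like nuclei under the stricter nuclei filter. Slit2 rose (1.16, SE 0.16) and Thsd7b fell (-1.05, SE 0.15) in conduction cardiomyocyte-like nuclei, each with adjusted p = 0.0461, and Inhba rose in cluster 18 (1.12, SE 0.12, adjusted p = 0.0253). These names too were chosen after their values were seen. Macrophage-like, megakaryocyte-like and mitochondria-rich ventricular nuclei had 0 genes past the edgeR test, with 211, 173 and 490 at an unadjusted p under 0.05. Over these 8 classes DESeq2 called 20 genes, and edgeR called 454 without the library labelled male control, 133 without the male knockout, 397 without the female control and 155 without the female knockout library.

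Sums over all nuclei, which need no clusters, had 185 genes higher and 185 lower among 19757. Tmem132d (3.90, SE 0.13, adjusted p = 0.00133), Car4 (3.65, SE 0.18), the claudin gene Cldn3 (2.54, SE 0.15), the sodium channel subunit gene Scn3b (1.85, SE 0.14), Shc3 (1.31, SE 0.12), Fads6 (1.23, SE 0.07), Plcxd3 (1.17, SE 0.10) and Angptl7 (1.12, SE 0.07) rose, as did Mylk, the kinase that activates smooth muscle myosin (0.75, SE 0.05), and Gpr39 (0.75, SE 0.06). Hpse2, a heparanase family gene (-2.13, SE 0.15), the prolactin receptor gene Prlr (-2.06, SE 0.16), the cadherin gene Cdh10 (-1.60, SE 0.06, adjusted p = 0.00161), Nmnat3 (-1.15, SE 0.07), the potassium channel gene Kcnn3 (-0.94, SE 0.07), the transcription factor gene Ebf3 (-0.79, SE 0.05), Slc24a2 (-0.69, SE 0.04), the thrombospondin gene Thbs2 (-0.63, SE 0.05), Tenm4 (-0.60, SE 0.05) and Snap91 (-0.57, SE 0.05) fell. Such sums move with the share of each class as well as with expression. Tbx18 was lower as well (-0.70, SE 0.11, adjusted p = 0.0439), a call lost with doublets kept (adjusted p = 0.0746), under the stricter nuclei filter (0.0509), with 1 doublet limit (0.0588), without the female control (0.076) and without the female knockout library (0.155).

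Among lists in all nuclei, mitosis genes were higher (median 0.21, adjusted p = 3.77e-06, and adjusted p = 0.902 with an estimated correlation), with Ccnb1 (0.42, SE 0.07) as the only 1 of 22 past the test and 15 when adjusted over the list alone. Cardiac ion handling genes were lower (median -0.16, adjusted p = 0.00123, and adjusted p = 0.93 with an estimated correlation), with 2 of 15 past the test, the calcium channel gene Cacna1c (-0.37, SE 0.06) and the exchanger gene Slc8a1 (-0.42, SE 0.07), and 9 when adjusted over the list alone. DESeq2 called 1284 genes. Only 39 were called with doublets kept, 188 under the stricter nuclei filter and 134 with 1 doublet limit. The count was 1750 without the library labelled male control, 79 without the male knockout, 168 without the female control and 7 without the female knockout library.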

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

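The tests of mixed-in knockout material, of a wrong label and of a pooled embryo with Cre were chosen after the Cre values had been seen, while the odds ratio for index hopping was set beforehand and its reading by the GFP level was not. Cre and GFP stand out because they are signals outside the comparisons of mouse genes and lie above the level of a control library. The library labelled male control held 531 Cre UMIs against 0 in the female control library, and the described genotype of controls has no Cre. GFP in epicardial-like nuclei was 68.6 CPM in the male knockout and 76.6 in the female knockout.

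Nuclei or RNA of a knockout library mixed into the library labelled male control, and knockout reads assigned to it during sequencing (index hopping), would bring GFP and Cre together, and are argued against by 0.228 GFP UMIs per Cre UMI there (upper 95% bound 0.278), below the 1.328 and 1.503 of the male and female knockouts. A knockout sample under the control label is argued against by epicardial Tbx18 at 1.05 times the level of the female control library (460.2 and 438.0 CPM of the total UMIs of the class, without TMM). A pooled embryo with Tbx18Cre and the knockouts' Cre level in each class would give every class the same part of the knockout level. The ratio to the knockouts was instead 0.255 in epicardial-like nuclei and 0.625 over 5 other classes (quotient 0.408, 95% interval 0.264 to 0.632). A pooled embryo with Tbx18Cre but intact Numb and Numbl could have other Cre levels. The quotient cannot decide on such an embryo, which stays open. For hopping, of 631 shared barcodes, 23 had Cre in the library labelled male control and 3 had it in both, an odds ratio of 1.70 (0.53 to 5.47) that decides nothing alone, since its interval holds both 1 and the 5 set for hopping. Another construct with Cre in that sample stays open and was not tested, and no biological explanation was tested.

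For the share of coronary endothelial-like nuclei, both sexes moved in opposite directions, with a log2 ratio of knockout to control of 0.327 in the male pair and -0.222 in the female pair, a difference that was not tested. It depends on the clusters: both pairs were higher with clusters made without the changed genes (0.498 and 0.119), with low-UMI clusters named (0.477 and 0.053) and under the strict filter (0.549 and 0.491). The share of erythroid-like nuclei had a log2 ratio of -0.427 in the male pair and 0.412 in the female pair, also not tested.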

How the results depend on the processing

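The alternatives with 1 doublet limit, low-UMI clusters named, single mural clusters, the mitochondria-rich cluster included, clusters made without changed genes and the nuclei of named classes as library size were chosen after seeing the data; the others were planned. No gene called in the 7 main classes or in all nuclei changed direction under any alternative run. Changed genes were 997 in epicardial-like nuclei, 1571 without a filter on low counts and 536 under the strict nuclei filter, and 569 to 1573 when a library was left out (the library then alone in its group is assumed to vary like the other group). For fibroblast-like nuclei (319) they were 154 with DESeq2, 670 without the filter and 306 to 489 with a library left out. For mural-like nuclei (0) they were 2 with DESeq2, 157 without the filter, 3 in cluster 25 alone and 0 to 167. For ventricular cardiomyocyte-like nuclei (2) they were 15 with DESeq2, 281 without the filter, 1 with doublets kept, 1 with the mitochondria-rich cluster included and 6 to 205. For atrial cardiomyocyte-like nuclei (8) they were 5 with DESeq2 size factors, 2 with DESeq2, 53 without the filter, 0 with doublets kept, 0 under the strict filter, 4 with 1 doublet limit and 3 to 85. For endocardial-like nuclei (2) they were 13 with DESeq2, 355 without the filter, 0 with doublets kept, 0 under the strict filter and 9 to 87. For coronary endothelial-like nuclei (12) they were 51 with DESeq2, 470 without the filter, 49 with doublets kept, 52 with 1 doublet limit, 23 with low-UMI clusters named and 30 to 183. For all nuclei (370) they were 1284 with DESeq2, 1514 without the filter, 39 with doublets kept, 188 under the strict filter, 134 with 1 doublet limit and 7 to 1750. For the other classes (42) they were 20 with DESeq2, 743 without the filter, 10 with doublets kept, 2 under the strict filter and 133 to 454. Calls of Numb, Numbl and Tbx18 within classes, all nuclei not counted, (2) were 1 with DESeq2 size factors, 1 with DESeq2, 6 without the filter, 1 with doublets kept and 1 to 5. List calls in the 7 main classes, all nuclei and the other classes not counted, (49) were 0 with an estimated correlation, 6 with fry and 31 to 55. Classes called by share (1) were 2 under the strict filter, epicardial-like nuclei among them (log2 fold change 1.02), 0 with low-UMI clusters named, 0 when these clusters were also made without changed genes, and 0 to 1. The replicate number marks the sex, and the labels give nothing else that only the 2 libraries of a pair share. Deviations from the group means correlated at -0.001 in ventricular cardiomyocyte-like to 0.159 in coronary endothelial-like nuclei across genes of the 7 main classes. The correlation was 0.163 in all nuclei and ran from -0.064 in mitochondria-rich ventricular to 0.106 in cluster 18 and 0.447 in macrophage-like nuclei elsewhere. Xist and Y-linked genes were left out throughout. With the replicate number, and so the sex, as a block the counts were 1215 in epicardial-like, 689 in fibroblast-like, 0 in mural-like, 222 in ventricular, 66 in atrial, 39 in endocardial-like and 252 in coronary nuclei, 654 in the other classes (13 higher and 90 lower in macrophage-like nuclei, 212 and 175 in cluster 18), 1772 in all nuclei and 4 for the targeted genes, with Tbx18 in ventricular cardiomyocyte-like nuclei at adjusted p = 1.17e-13. Values that changed sign belong to results that had not passed. With a library left out they range from -0.002 to 0.29 for Numb in epicardial-like nuclei, -0.43 to 0.021 for Numb in mural-like nuclei, -0.44 to 0.25 for Numbl in ventricular cardiomyocyte-like nuclei, -0.067 to 0.075 for Numb in atrial cardiomyocyte-like nuclei, -0.36 to 0.58 for Numbl in atrial cardiomyocyte-like nuclei, -0.30 to 0.16 for Numbl in endocardial-like nuclei, -0.032 to 0.012 for Numb in all nuclei, -2.87 to 0.71 for Myh11 in coronary endothelial-like nuclei, -0.12 to 0.21 for the share of coronary endothelial-like nuclei and -0.34 to 0.021 for the share of valve mesenchyme-like nuclei. These are, with doublets kept, Col23a1 in mural-like nuclei (0.37), Rasgef1b in mural-like nuclei (0.34), Fabp4 in mural-like nuclei (0.10) and Emcn in mural-like nuclei (0.38); Emcn also under the strict filter (0.082), with 1 doublet limit (0.057) and in cluster 25 alone (0.44), and Abcc9 in mural-like nuclei in cluster 17 alone (0.084). With the mitochondria-rich cluster included they are mt-Atp8 in ventricular cardiomyocyte-like nuclei (0.06), mt-Cytb in ventricular cardiomyocyte-like nuclei (0.12), mt-Co3 in ventricular cardiomyocyte-like nuclei (0.14), mt-Nd4 in ventricular cardiomyocyte-like nuclei (0.25) and Numbl in ventricular cardiomyocyte-like nuclei (0.13). With low-UMI clusters named they are mt-Cytb in fibroblast-like nuclei (0.03), mt-Nd2 in fibroblast-like nuclei (0.028) and mt-Co2 in fibroblast-like nuclei (0.017). Under the strict filter they are mt-Nd4 in coronary endothelial-like nuclei (0.025), Numb in all nuclei (0.047) and the share of valve mesenchyme-like nuclei (0.17; 0.013 with named classes as library size). With only pure neighbours they are Numb in atrial cardiomyocyte-like nuclei (-0.022) and Tbx18 in coronary endothelial-like nuclei (0.07), and with 1 doublet limit Numbl in atrial cardiomyocyte-like nuclei (-0.015). In the other classes the sign also changed with a library left out for Numb (to 0.011) and Numbl (to 0.131) in valve mesenchyme-like and for Numb (to 0.103) and Numbl (to -0.136, and -0.143 with low-UMI clusters named) in mitochondria-rich ventricular nuclei, and under the strict filter for Numb in cluster 18 (0.071). The cause of these shifts was not tested. Counted by setting, results that weakened were 3 with DESeq2 size factors, 19 with DESeq2, 22 with doublets kept, 26 under the strict filter, 10 with pure neighbours, 10 with 1 doublet limit, 4 with low-UMI clusters named, 51 with fry and 56 with an estimated correlation (these include lists in all nuclei), and 16, 31, 39 and 65 without the library labelled male control, the male knockout, the female control and the female knockout library. Small changes are missed at this depth and number of libraries: simulated 1.5-fold changes were recovered at 40.9% in epicardial-like, 33.3% in fibroblast-like and 13.8% in mural-like nuclei. The strict filter was not run in mitochondria-rich ventricular, erythroid-like and megakaryocyte-like nuclei, which kept under 20 nuclei in a library, and the count of nuclei kept has no test.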

Other observations

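The tests of free RNA that follows the fibroblast number and of UMIs per nucleus in coronary endothelial-like nuclei, and the genes named in the first paragraph were chosen after the values had been seen. In epicardial-like nuclei, genes for signals that the epicardium can send to its neighbours moved both ways. Nrg1, a neuregulin that acts on cardiomyocytes through ERBB receptors, rose by a log2 fold change of 1.62 (SE 0.26, adjusted p = 0.00365), Slit2, an axon guidance ligand, by 1.17 (SE 0.14), the chemokine gene Cxcl12 by 0.88 (SE 0.17), and the vascular growth factor genes Vegfc and Vegfa by 0.82 (SE 0.14) and 0.79 (SE 0.14). The ligand genes Tgfb2 (-0.84, SE 0.14), Bmp4 (-0.52, SE 0.12) and Rspo1 (-0.63, SE 0.12) fell. Of 27 epicardial secreted factors 5 rose and 3 fell, 7 and 8 when adjusted over the list alone, and the list was not called (median -0.07, adjusted p = 0.849). In the BMP and TGF-beta list (median 0.34, adjusted p = 0.203, not called) 6 of 20 rose and 5 fell, 10 and 6 when adjusted over the list alone. The binding protein gene Ltbp2 rose by 2.28 (SE 0.16) and the inhibitor gene Smad7 by 1.36 (SE 0.13), while the ligand genes Bmp5 (-2.28, SE 0.44) and Bmp2 (-1.34, SE 0.31) fell. Among 19 Wnt genes (median -0.19, adjusted p = 0.348, not called) 3 rose and 4 fell, 3 and 9 when adjusted over the list alone, with Wnt11 at 1.36 (SE 0.18) and Wnt2b at -0.80 (SE 0.12).

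Glycolysis genes were called higher in further classes: valve mesenchyme-like (median 0.29, adjusted p = 0.000124, and adjusted p = 0.873 with an estimated correlation), conduction cardiomyocyte-like (0.25, adjusted p = 0.00985, and adjusted p = 0.989 with an estimated correlation), macrophage-like (0.38, adjusted p = 0.00269, and adjusted p = 0.929 with an estimated correlation) and erythroid-like nuclei (0.67, adjusted p = 2.06e-05, and adjusted p = 0.748 with an estimated correlation). No member passed over all genes, and 7, 6, 0 and 1 did when adjusted over the list alone. Mitochondrially encoded RNA was lower beside them in valve mesenchyme-like (median -0.19, adjusted p = 0.0103, and adjusted p = 0.873 with an estimated correlation) and conduction cardiomyocyte-like nuclei (-0.27, adjusted p = 0.000512, and adjusted p = 0.989 with an estimated correlation), where 0 and 8 members passed when adjusted over the list alone. In macrophage-like nuclei extracellular matrix genes were lower (median -0.71, adjusted p = 6.3e-11, and adjusted p = 0.929 with an estimated correlation), with no member past the test in either count, and the fibroblast markers were lower beside them (median -1.02, 15 of 15 lower).

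As a hypothesis, knockout epicardial-like nuclei may have moved part of the way toward a fibroblast profile. Genes of at least 20 CPM in fibroblast-like nuclei, and at least 4 times higher there than in epicardial-like nuclei of the control library of 1 sex, were measured in the pair of the other sex, and their median log2 fold changes were 0.402 in the male pair (374 genes) and 0.496 in the female pair (342 genes). The 20 fibroblast markers fixed beforehand did not move as a set (median -0.004, 11 lower and 9 higher). Fibroblast nuclei or RNA among the epicardial-like nuclei are argued against only as the source of the whole Pdgfra rise. That rise would need a share of 37.8% fibroblast RNA, and 1 of the 20 most abundant fibroblast genes reached at least 0.5 of the rise that this share would give. A smaller share could still raise fibroblast genes, was not tested and stays open. The changes were uneven from controls to knockouts: Gpc6 went from 408.85 to 1005.28 CPM, Postn from 103.13 to 106.96 and Ebf2 from 5.85 to 1.59. A change of cell state within the epicardium and a change in which epicardial nuclei were captured stay open.

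Fibroblast markers were lower in several classes that are not fibroblasts, with medians of -0.72 in coronary endothelial-like, -0.37 in atrial cardiomyocyte-like and -1.02 in macrophage-like nuclei (male pair -0.41, female pair -1.18). Free RNA that follows the smaller number of fibroblast-like nuclei would lower them in every class, but in erythroid-like nuclei the median was 0.119 (quartiles -0.045 and 0.496). There 6 of 14 markers were lower and 8 higher. That class was shallow, with 0.33 M UMIs in the male knockout and a median SE of 0.396 over its genes. Ebf1, not among these markers but at 3124 CPM in knockout fibroblast-like nuclei, fell there by 2.29. The erythroid-like median alone therefore does not exclude such RNA. Marker levels are CPM, so the number of UMIs per nucleus need not move them by itself. The UMI counts below therefore cannot settle why the markers fell. Fewer UMIs per nucleus in the knockout are argued against for coronary endothelial-like nuclei of the male pair only in that they were not fewer. There the median was 1.128 times the control (95% interval 1.053 to 1.203) while the markers fell (median -1.105, upper quartile -0.783). That interval comes from resampling nuclei of 1 control and 1 knockout library and holds no variation between libraries. In the female pair the median was 6329 UMIs in the control and 5943 in the knockout, with the markers at -0.267, so fewer UMIs stay open there. For macrophage-like nuclei they stay open: the test set beforehand, the highest knockout over the lowest control median (1.27 in erythroid-like and 1.04 in macrophage-like nuclei), compares across the sexes, and within the male and female pairs the macrophage ratios were 0.917 and 0.903. In atrial cardiomyocyte-like nuclei of the male pair the median UMIs were not lower (5022 in the control, 5024 in the knockout), while the markers fell (median -0.406). In the female pair they were 4875 and 4754.5, with the markers at -0.146. Doublets with fibroblasts, fewer UMIs in atrial nuclei of the female pair and true changes in these classes stay open as possible explanations and were not tested.

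A further hypothesis was that genes changed in several classes at once lie in DNA of another strain carried along with the targeted alleles. Of the 112 genes called in at least 2 classes, 3 lay within 20 Mb of a targeted locus, against 7.41% of the other genes tested (odds ratio 0.344, Fisher's exact p = 0.0664). These genes were thus not enriched near the loci. Most of them were called in epicardial-like and fibroblast-like nuclei, and classes with few calls could add few genes. The test therefore does not exclude such DNA. Free RNA of the classes that changed could not be decided, as 43 of these 112 genes (38.4%) were at least 4 times higher in control epicardial-like or fibroblast-like nuclei than in the median class. One of the 3 is Nt5e (chromosome 9, 88327197 to 88372092), beside Tbx18, which moved both ways among its 4 classes. Nmnat3 (chromosome 9, 98287435 to 98420438) and Snap91 (chromosome 9, 86765923 to 86880654), both lower in all nuclei, lie on the chromosome of Tbx18 (87702800 to 87731260). These positions were looked up after the values had been seen. Neither Nmnat3 nor Snap91 was called in 2 or more classes, so the test above does not cover them, although both lie within 20 Mb of Tbx18.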
